A study of Mus musculus with 9 samples.

How the data were processed

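Uterine luminal epithelium was collected by laser capture from female mice on pregnancy day 4, after the females had been kept to 8 weeks of age, per the labels. There were 3 genotypes with 3 libraries each. Wnt7acre mice carried the cre recombinase alone and were the controls. The ePRAoe mice (Wnt7acre/+PgrALsL/+) were made to overexpress progesterone receptor isoform A in the epithelium, and the ePRBoe mice (Wnt7acre/+PgrBLsL/+) isoform B. The labels number the bioreplicates and do not name the animals, so the p-values measure the spread between these 9 samples. Total RNA was extracted with Trizol, cleaned on RNeasy columns and made into Illumina libraries, per the labels' protocols.

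The authors' values were held as 1 deposited table of FPKM (fragments per kilobase of gene, scaled to the library's depth) for 15158 gene symbols in 9 libraries, per the file headers. Reads had been aligned to mm10 with STAR 2.5.2b and counted per gene with featureCounts 1.5.0-p1 of Subread, and edgeR 3.28.0 and limma 3.42.2 had been used downstream, per the submitters' processing notes. The annotation, the strand setting and the gene lengths behind the deposited FPKM are not given in the sources used here. The values are per gene, so the transcripts of isoforms A and B were not told apart. Of the symbols, 14970 (98.8%) were found in GENCODE M21, from which gene identifiers and mm10 positions were taken.

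The table holds no read counts, and the depth of each library is not stated. The low values nevertheless fell on steps: of 860 genes with a maximum under 0.6 FPKM and at least 6 libraries above 0, 41.4% had all libraries on multiples of 1 common step of at least 0.02 FPKM within a tolerance of 0.0006, against 0% when values were shuffled between genes. A read was thus worth about the same FPKM in each library. With annotated exonic lengths the steps implied a median of 11.9 M reads per library (quartiles 8.71 and 13.1 over 345 genes), so that 1 FPKM stood for about 23.8 reads of a gene of 2 kb. This figure is approximate, since FPKM times annotated length summed to 121% to 131% of what the scaling allows. No counting interval was computed from it.

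The order of the table was examined after its values had been seen. Of the 15158 symbols, 4239 stood out of alphabetical order among 10919 ordered ones, and 1896 of the 1998 genes later called between ePRAoe and Wnt7acre were among the 4239. Whether each name still belonged to its values was tested with the gene length implied by the step of low genes (maximum under 3 FPKM). That length correlated across genes with the annotated exonic length both in the rows out of order (Spearman's rho 0.785, 296 genes) and in the rows in order (0.690, 1678 genes), against at most 0.109 and 0.0658 over 200 shuffles of the names. All rows were therefore used. Genes are not independent replicates, and no p-value was drawn from these correlations.

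Values were transformed as log2(FPKM + 1), and all folds are on that scale. The 12347 genes with at least 1 FPKM in at least 3 libraries were tested, and 2811 were not. limma 3.58.1 in R 4.3.3 fitted all 9 libraries with a term for each genotype and for the sequencing run, with moderated variances that followed the expression trend (4 residual and 3.64 prior degrees of freedom). The 3 runs came from the labels. Run 1 held Wnt7acre replicate 3, ePRAoe replicate 2 and ePRBoe replicates 1 to 3, run 2 held Wnt7acre replicate 2 and ePRAoe replicate 3 (both runs in 2019), and run 3 held Wnt7acre replicate 1 and ePRAoe replicate 1 (2020). The 3 comparisons were ePRAoe with Wnt7acre, ePRBoe with Wnt7acre and ePRBoe with ePRAoe, each two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The samples, the test, the gene lists, the naming rule and the settings to be varied were fixed before the data were examined. For Pgr an exact permutation test was run beside limma.

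There were 22 gene lists, of which 20 had at least 3 tested members. The list of red blood cell genes had 1 member in the table and that of mitochondrial transcripts had 0, so neither was tested. Lists were tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes, with adjustment over the 20 lists of a comparison. Beside it stand camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance. The genes named were Pgr and Wnt7a; per comparison and direction the 10 largest log2 fold changes among called genes with no overlap of libraries and a mean of at least 5 FPKM in the higher group, without symbols of predicted genes; and up to 4 called members of each list with the largest moderated t. Where fewer than 5 genes passed, the 5 with the smallest unadjusted p were named as not passing, and where fewer than 2 members of a list passed, the 2 with the highest mean FPKM were named. A few genes that this rule picks are not reported here.

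The procedure was tested on simulated data with 200 genes changed. At a 4-fold change it recovered 93.8% of the changed genes for ePRAoe against Wnt7acre (12093 genes in the fit), 90.6% for ePRBoe against Wnt7acre (12077) and 85.7% for ePRBoe against ePRAoe (12097). At a 2-fold change the shares were 60%, 26.2% and 23.9%, and at 1.5-fold 3.08%, 0% and 0%. False calls were 5 of 107, 2 of 77 and 2 of 72, and no changed gene was called in the wrong direction. The simulated noise was independent between genes and held no run effect, so the share of false calls in the real data may be higher. A list shifted by 1 on the log2 scale, that of stroma markers, was called in both simulated comparisons that held the shift. Beside it 2 other lists were called for ePRAoe against Wnt7acre, and 0 for ePRBoe against Wnt7acre. The shifted list shares 4 genes with other lists, so not all of those were free of the shift.

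The settings varied were pseudocounts of 0.1 and 5, no filter or a mean of at least 5 FPKM, rescaling to TPM, median-of-ratios factors, quantile normalization, other treatments of the run and of the replicate number, fits of the 2 groups compared, other variance models, a fold of at least 1.5, the other list tests, and leaving out each library in turn. With the run term, leaving out either the Wnt7acre or the ePRAoe library of a run drops that run from their comparison. A score of stroma markers as a covariate and a fit without run 3 were added after the data had been seen. Figures were drawn with matplotlib 3.10.9, and tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

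All 150 named genes had a position in the annotation. For 2 of them over 20% of the exonic length was shared with another tested gene: Catsperz shared 46.5% with Kcnk4 on the same strand, and Hoxa11 shared 35.0% with Hoxa11os on the opposite strand. With genes that were not tested, all on the opposite strand, Ccdc3 shared 69.1% (Gm26776), Fxyd3 42.45% (Lgi4) and Fbn1 20.1% (Gm9913). Near-identical members of the Sprr2, Klra, Hist1h and Ifit families can share reads, which the deposited FPKM do not resolve.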

Results

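RNA of uterine luminal epithelium, the cell layer that an embryo first attaches to, was sequenced from laser-captured tissue of mice on pregnancy day 4, when the uterus becomes receptive. There were 3 libraries each of Wnt7acre (control), ePRAoe (progesterone receptor isoform A overexpressed in the epithelium) and ePRBoe (isoform B overexpressed). The values summed to between 272213 and 314010 FPKM per library, and 11074 to 12300 genes reached 1 FPKM. The 50 highest genes took 10.5% to 13.6% of the FPKM of a library. Replicates correlated across genes at 0.932 to 0.964 in Wnt7acre, 0.929 to 0.965 in ePRAoe and 0.970 to 0.974 in ePRBoe. The first principal component (47.1% of the variance) placed the Wnt7acre libraries at -31.6, -69.5 and -44.2 and the other 6 between 11.5 and 38.2.

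Pgr, which was overexpressed by design in ePRAoe and ePRBoe, was higher in both overexpressing genotypes and alike in them. Of 18 stroma markers 11 and 14 were higher in these genotypes too, and the values do not show which cells the Pgr reads came from. Pgr (ENSMUSG00000031870.16, chromosome 9, 8899833 to 8968611, forward strand, mm10) stood at 17.4, 3.82 and 6.62 FPKM in Wnt7acre replicates 1 to 3, at 41.7, 49.5 and 42.8 in ePRAoe and at 38.1, 38.3 and 45.9 in ePRBoe. The means were 9.28 ± 7.17, 44.7 ± 4.19 and 40.8 ± 4.48 FPKM (SD, n = 3). Pgr rose by 2.38 on the log2 scale (SE 0.33, 5.19-fold, adjusted p = 0.00483) in ePRAoe and by 2.27 (SE 0.40, 4.84-fold, adjusted p = 0.0168) in ePRBoe, higher in 3 of 3 libraries each. Between ePRBoe and ePRAoe the difference was -0.10 (SE 0.40, adjusted p = 0.911). The two-sided exact permutation test gave p = 0.1, 0.1 and 0.3 for the 3 comparisons, and 0.1 is the smallest that 20 regroupings of 3 against 3 allow. Within run 1, run 2 and run 3 the log2 difference of ePRAoe from Wnt7acre was 2.73, 3.18 and 1.22, and within run 1 that of ePRBoe from Wnt7acre was 2.45. The ePRBoe call was lost without Wnt7acre replicate 3 (1.92, adjusted p = 0.186), ePRAoe replicate 2 (2.45, 0.0561), ePRBoe replicate 2 (2.31, 0.0508) or ePRBoe replicate 3 (2.19, 0.0526). Wnt7a (chromosome 6, 91363981 to 91411363, reverse strand), the gene that the cre line is named after, had means of 56.8 ± 13.8, 20.8 ± 13.9 and 28.9 ± 18.8 FPKM (SD, n = 3). It fell by 1.57 in ePRAoe (SE 0.43, adjusted p = 0.0457) and did not pass in ePRBoe (-0.49, adjusted p = 0.605) or between ePRBoe and ePRAoe (1.07, adjusted p = 0.317). The Wnt7a call was lost without Wnt7acre replicate 2 or 3, ePRAoe replicate 2 or 3 (adjusted p = 0.193 to 0.194) or ePRBoe replicate 2 (0.0708).

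**Figure D1:**
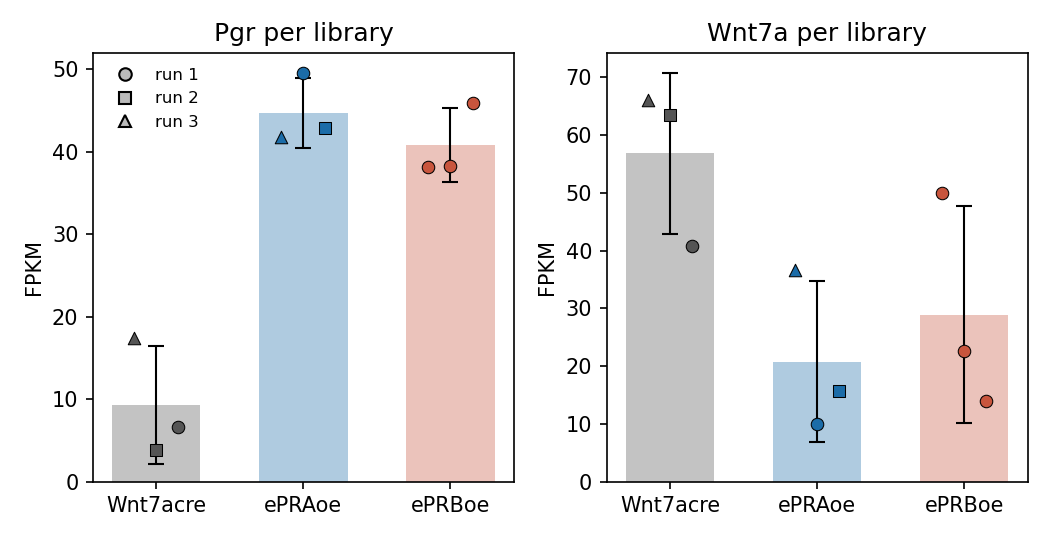
FPKM of Pgr and Wnt7a in each library (points), with the mean and SD of the 3 libraries per genotype. Pgr lay between 38.1 and 49.5 FPKM in all 6 overexpressing libraries and between 3.82 and 17.4 in the Wnt7acre libraries.

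The comparison of ePRAoe with Wnt7acre asks what extra isoform A changes in the luminal epithelium. Of 22 progesterone-induced genes 8 rose, among them Gata2 and Hsd11b2, and of 18 stroma markers 11 rose, Col6a1 among them (camera called both lists, adjusted p = 0.46 with an estimated correlation). Of 18 interferon-induced genes 5 fell, Ifit3 among them, and of 15 immune cell markers 4 fell (camera called both, adjusted p = 0.83 and 0.46 with an estimated correlation). Gabrp, Depp1 and Mmp7 also fell. In all, 889 genes rose and 1109 fell (1998 of 12347, 16.2%), 837 and 1044 of them by at least 1.5-fold.

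Nnat, a small membrane protein of the endoplasmic reticulum, rose most (log2 fold change 4.60, adjusted p = 0.0129), from 2.05 ± 0.205 to 135 ± 116 FPKM (SD, n = 3). Spink8, a serine protease inhibitor, rose by 4.48 (adjusted p = 0.00439), from 2.87 ± 1.8 to 102 ± 78.9 FPKM. Drd4, a dopamine receptor, rose by 3.46, and Slc39a2, a zinc importer, by 3.39 (1.73 ± 1.34 to 25.8 ± 6.74 FPKM, adjusted p = 0.00266). Sprr2g (small proline-rich protein, 3.38), Nptx1 (pentraxin, 3.34), Catsperz (3.33), Areg (amphiregulin, 3.19), Suox (sulfite oxidase, 3.11) and Ccdc3 (3.11) made up the rest of the 10 largest rises. Nnat, Sprr2g, Nptx1, Catsperz and Areg lost the call without Wnt7acre replicate 3 (adjusted p = 0.0817, 0.0625, 0.0822, 0.097 and 0.144) or without ePRAoe replicate 2 (0.082, 0.0622, 0.0834, 0.0972 and 0.145). All but Sprr2g of these also lost it without Wnt7acre replicate 2 or ePRAoe replicate 3 (0.0788 to 0.144). Gabrp, a GABA receptor subunit, fell by 6.36 (SE 0.22, adjusted p = 5.07e-05), from 134 ± 58.5 to 0.595 ± 0.475 FPKM. Depp1, a target of FOXO factors, fell by 6.25 (330 ± 151 to 7.7 ± 11.6 FPKM), Mmp7, a matrix metalloprotease, by 5.93 (249 ± 165 to 2.8 ± 2.8) and Gpx3, a secreted glutathione peroxidase, by 5.17 (306 ± 239 to 4.37 ± 0.897). Chil1, Ttpa, Ggh, Cyp2s1, Ifit1bl1 and Ifit3b fell by 5.17, 4.92, 4.78, 4.71, 4.62 and 4.55, and all 10 falls passed with any 1 library left out.

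Of the 22 tested progesterone-induced genes, 8 rose and 0 fell, and 11 rose and 1 fell adjusted over the list alone, with a median log2 fold change of 0.76. Camera placed the list above other genes (adjusted p = 7.78e-06), with adjusted p = 0.46 with an estimated correlation. Gata2, a transcription factor downstream of the receptor, rose by 1.68 (41.1 ± 17.4 to 131 ± 49.5 FPKM, adjusted p = 0.00219), Hsd11b2, which inactivates corticosterone, by 1.39, Lrp2 by 1.15 and Sox17 by 1.28, the last of which lost the call without Wnt7acre replicate 3 (0.0635) or ePRAoe replicate 2 (0.0631). Among 13 prostaglandin pathway genes 3 rose and 1 fell (4 and 1 adjusted over the list alone, median 0.41, camera 0.0390, adjusted p = 0.572 with an estimated correlation). Pla2g4a, which frees arachidonic acid, rose by 1.13 and Pla2g10 by 2.32 (23.3 ± 16.9 to 93.7 ± 15.8 FPKM), while Ptgs2 (cyclooxygenase 2) rose by 2.83 and Ptger2 fell by 0.73. Of 8 hedgehog pathway genes 2 rose and 0 fell, in both adjustments (median 0.54, camera 0.0426, adjusted p = 0.772 with an estimated correlation), with Gli1 at 1.12. Ptgs2, Ptger2 and Gli1 lost the call without Wnt7acre replicate 2 (adjusted p = 0.111, 0.0563 and 0.0563) among other libraries. The prostaglandin list lost its call without Wnt7acre replicate 2 (0.0766), Wnt7acre replicate 3 (0.0855), ePRAoe replicate 2 (0.0794) or ePRAoe replicate 3 (0.0693), and the hedgehog list without Wnt7acre replicate 1 (0.0504), Wnt7acre replicate 2 (0.230) or ePRAoe replicate 3 (0.219). Over genes with a mean of at least 5 FPKM the hedgehog list did not pass (median 0.22, 0.687), and with median-of-ratios factors neither list did (0.0514 each).

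Of 18 stroma markers, genes of the connective tissue beneath the epithelium, 11 rose and 0 fell, and 15 rose adjusted over the list alone (median 1.14, camera 8.78e-10, adjusted p = 0.46 with an estimated correlation). Col6a1 rose by 1.59 (9.11 ± 1.94 to 29.6 ± 6.35 FPKM), Col3a1 by 1.57, Fbn1 by 1.37 and Dpt by 2.28. Of 15 immune cell markers 0 rose and 4 fell, and 10 fell adjusted over the list alone (median -0.73, camera 0.000141, adjusted p = 0.46 with an estimated correlation). Tyrobp, a signalling adaptor of myeloid and natural killer cells, fell by 1.11 (53 ± 21.4 to 23.2 ± 7.29 FPKM), Fcer1g by 0.97, C1qc by 0.91 and Csf1r by 0.85. No endothelium marker of 9 passed in limma or adjusted over the list alone, and 0 had an unadjusted p under 0.05 (median 0.27, camera 0.634). No smooth muscle marker of 5 passed in either adjustment, and 1 had an unadjusted p under 0.05 (median 0.02, camera 0.667). Of 18 interferon-induced genes 0 rose and 5 fell, and 13 fell adjusted over the list alone (median -1.32, camera 1.5e-05, adjusted p = 0.83 with an estimated correlation). Ifit3 fell by 4.18 (44.1 ± 11.3 to 1.66 ± 1.38 FPKM, adjusted p = 0.00116), Rsad2 by 3.41, Oas2 by 2.91 and Ifi44 by 2.53. C1qc, Csf1r, Oas2 and Ifi44 lost the call without at least 1 library (highest adjusted p = 0.0563, 0.126, 0.057 and 0.194, the first without Wnt7acre replicate 2 and the others without Wnt7acre replicate 3).

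Camera called none of the lists that follow. Estrogen-induced epithelial genes had 5 that rose and 6 that fell of 17 (5 and 7 adjusted over the list alone, as in the brackets that follow, camera 0.448): Wnt7b fell by 4.12 (108 ± 66.7 to 5.18 ± 4.05 FPKM), Myc by 1.96, Muc4 by 1.51 and Lcn2 by 1.94, while Fos rose by 2.79. Of 27 implantation and receptivity genes 5 rose and 3 fell (9 and 5, camera 0.294), with Hoxa11 up by 1.45, Msx1 by 1.27 and Lpar3 from 60.8 ± 33.8 to 114 ± 43.4 FPKM, and Spp1, a secreted attachment protein, down (-3.41). Hoxa11 is also among the stroma markers. Luminal epithelium markers had 3 rises and 5 falls of 20 (4 and 7, camera 0.634), including Spint1 (-1.30), Met (-2.11) and Esrp1 (0.61). Gland markers had 2 of each among 8 (2 and 2, camera 0.968), with Spink1 at -3.97, Aldh1a1 at 1.58 and Calb1 at 1.72. The Wnt pathway list had 2 rises and 4 falls of 22 (3 and 4, camera 0.828), with Lgr5, a marker of epithelial progenitors, at -2.76 (55.2 ± 24.2 to 10.1 ± 9.22 FPKM), Lef1 at 0.96 and Sfrp1 at -0.88. Ion and water transport genes had 2 rises and 4 falls of 17 (3 and 4, camera 0.652). Scnn1g, a subunit of the epithelial sodium channel, fell from 6.31 ± 4.16 FPKM to a level listed at 0 in all 3 ePRAoe libraries (adjusted p = 0.00219), and Scnn1b fell by 1.64, Fxyd3 fell by 0.96 and Fxyd4 rose by 1.61. EGF receptor genes and ligands had 2 rises and 3 falls of 9 (4 and 4, camera 0.948), with Erbb3 at -0.93 and Btc at -1.22 among the falls and Areg among the rises. Tight junction genes had 1 rise and 2 falls of 22 (1 and 2, camera 0.294), with Cldn10 at -2.88 and Cldn8 at -1.35. Cell cycle genes had 2 rises and 0 falls of 25 (1 and 0, camera 0.920, Tyms 1.21, Top2a 1.38), and immediate early and heat shock genes 3 rises and 1 fall of 15 (3 and 1, camera 0.263, Dusp1 1.72, Egr1 1.45, Hspb1 -0.74). The mean log2(FPKM + 1) of the latter list was 5.34 in ePRAoe replicate 2, against 4.15 and 4.35 in ePRAoe replicates 1 and 3. Of 20 cholesterol synthesis genes 0 rose and 3 fell (0 and 3, camera 0.738, Fdft1 -0.62, Mvd -0.81), and of 14 steroid receptor genes Pgr alone passed in both adjustments (camera 0.828), with Fkbp4 (-0.46, adjusted p = 0.132) and Pgrmc1 (0.14, 0.617) not passing. Without Wnt7acre replicate 3 the calls of Lcn2, Msx1, Esrp1, Calb1, Lgr5, Scnn1b, Fxyd4, Btc, Cldn10, Top2a, Dusp1, Egr1, Hspb1, Fdft1 and Mvd were lost (adjusted p = 0.0503 for Msx1 to 0.139 for Top2a), as they were without ePRAoe replicate 2. Those of Lpar3 and Lef1 were lost without Wnt7acre replicate 2 (0.0639 and 0.117) or ePRAoe replicate 3 (0.0612 and 0.118), and that of Sfrp1 without ePRAoe replicate 1 (0.0919), 2 (0.0718) or 3 (0.141) or ePRBoe replicate 1 (0.0687) or 2 (0.0527).

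Of the 1998 calls, 87.4% had no overlap between the 3 libraries of each genotype, against 28.9% of all genes and 10% by chance. Calls were chosen by the difference between these same libraries, so a high share among them follows largely from that choice. The count was 757 without Wnt7acre replicate 2, 723 without Wnt7acre replicate 3, 747 without ePRAoe replicate 2 and 802 without ePRAoe replicate 3. With median-of-ratios factors 988 genes rose and 1078 fell, with quantile normalization 962 and 967, and with TPM 961 and 945. Of the 76 called genes named here besides Pgr, 43 passed with any 1 library left out.

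**Figure D2:**
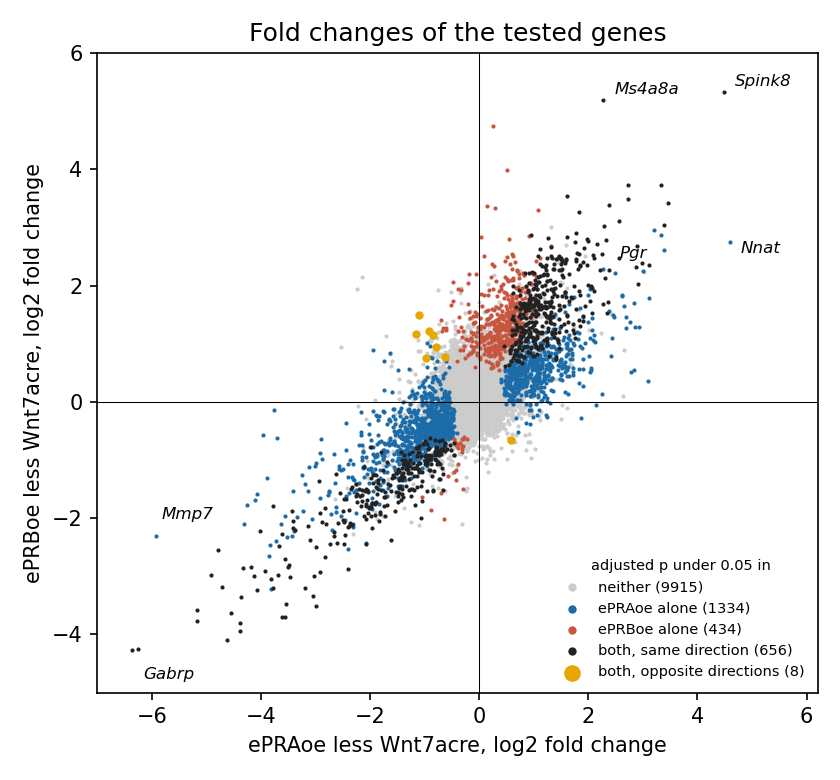
Log2 fold change of each tested gene in ePRAoe (x axis) and ePRBoe (y axis) against Wnt7acre, coloured by the comparisons in which the gene passed. In both comparisons 656 genes passed in the same direction and 8 in opposite directions.

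The comparison of ePRBoe with Wnt7acre asks the same of isoform B. Rises outnumbered falls, with Spink8, Ms4a8a and Slc5a5 among the rises and Gabrp, Depp1 and Olfm1 among the falls. Of 18 stroma markers 14 rose, Pdgfra among them, and of 15 immune cell markers 6 rose (camera called both lists, adjusted p = 0.411 with an estimated correlation). Of 25 cell cycle genes 5 rose, and of 22 progesterone-induced genes 5 rose, Hsd11b2 among them (camera called both, adjusted p = 0.506 with an estimated correlation). There were 792 genes that rose and 306 that fell (1098, 8.89%; 72.1% rose), 790 and 306 of them by at least 1.5-fold.

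Spink8 rose by 5.33 (2.87 ± 1.8 to 214 ± 70.3 FPKM, SD, n = 3, adjusted p = 0.00883) and Ms4a8a, a membrane protein of epithelia, by 5.19 (1.24 ± 0.808 to 93.3 ± 13.2 FPKM, adjusted p = 0.003). Calca, which encodes calcitonin, was listed at 0 in all Wnt7acre libraries and at 53.0, 29.3 and 10.2 FPKM in ePRBoe (adjusted p = 0.00765). Slc5a5, the sodium iodide symporter, rose by 3.73 (4.72 ± 1.74 to 132 ± 26.4 FPKM, adjusted p = 0.00317) and Pga5, a pepsinogen, by 3.38 (2.65 ± 1.19 to 64 ± 15.9 FPKM). Catsperz rose by 3.72, Sprr2f by 3.54, Sept4 by 3.48 and Drd4 from 7.06 ± 2.8 to 145 ± 22.3 FPKM. Gabrp fell by 4.26 (134 ± 58.5 to 5.65 ± 1.73 FPKM, adjusted p = 0.00169), Hal, which degrades histidine, by 3.93, Olfm1, a secreted glycoprotein, by 3.70 (353 ± 258 to 28.5 ± 15.2 FPKM) and Chil1 by 3.58. Depp1 fell by 4.24, Ifit1bl1 by 4.10, Pinlyp by 3.81, Gpx3 by 3.78, Zfp750, an epidermal differentiation factor, by 3.70 and Ifit3b by 3.63. Of these genes, Ms4a8a, Slc5a5, Pga5, Gabrp, Hal, Olfm1 and Chil1 passed with any 1 library left out. The others lost the call without Wnt7acre replicate 3, with adjusted p from 0.0562 (Sprr2f) to 0.341 (Gpx3), Spink8 at 0.108 and Calca at 0.0805.

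Of the 18 stroma markers 14 rose and 0 fell, and 17 rose adjusted over the list alone (median 1.88, camera 2.67e-13, adjusted p = 0.411 with an estimated correlation). Col6a1 rose by 2.43 (9.11 ± 1.94 to 48.1 ± 4.55 FPKM) and Pdgfra, a fibroblast receptor, by 2.36 (2.84 ± 0.872 to 20.6 ± 2.3 FPKM). Among 9 endothelium markers 2 rose and 0 fell in both adjustments (median 1.07, camera 0.00737, adjusted p = 0.506 with an estimated correlation), Cdh5 by 1.87 and Eng by 1.67, and the list call was lost without ePRAoe replicate 2 (0.0549). The mean log2(FPKM + 1) of the list was 3.09 in ePRBoe replicate 2, against 2.20 and 2.24 in ePRBoe replicates 1 and 3 and 1.25 to 1.65 in Wnt7acre. Of 5 smooth muscle markers Des rose by 1.90, and the list did not pass (median 1.29, camera 0.0863); Myl9 did not pass (1.29, adjusted p = 0.407), with 42.5 FPKM in ePRBoe replicate 2 against 7.58 and 5.26 in the other ePRBoe libraries. Immune cell markers had 6 rises and 0 falls of 15, and 11 rises adjusted over the list alone (median 0.94, camera 4.19e-06, adjusted p = 0.411 with an estimated correlation). Nkg7, a granule protein of natural killer and T cells, rose by 2.21 (6.11 ± 2.7 to 18.4 ± 3.04 FPKM), Tyrobp to 95 ± 10.4 from 53 ± 21.4 FPKM, Cd52 by 1.67 and Laptm5 by 1.15. Cdh5, Eng, Tyrobp, Cd52 and Laptm5 lost the call without Wnt7acre replicate 3 (adjusted p = 0.0505, 0.0607, 0.074, 0.147 and 0.176).

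Of the 22 progesterone-induced genes 5 rose and 0 fell, and 10 rose adjusted over the list alone (median 0.96, camera 6.84e-05, adjusted p = 0.506 with an estimated correlation). Hsd11b2 rose by 2.06 (12.2 ± 3.46 to 59.6 ± 9.3 FPKM, adjusted p = 0.00494) and Gata2 by 1.80, and the co-chaperone Fkbp5 by 1.26. Of 25 cell cycle genes 5 rose and 0 fell, and 12 rose adjusted over the list alone (median 0.77, camera 0.00092, adjusted p = 0.506 with an estimated correlation). Mki67 rose by 1.54 (5.73 ± 1.59 to 12.3 ± 1.95 FPKM), Plk1 by 1.38, Birc5 by 1.20 and Aurka by 0.97, and each of these 4 calls was lost without Wnt7acre replicate 3 (adjusted p = 0.101, 0.279, 0.188 and 0.112). Of 8 hedgehog pathway genes 4 rose and 0 fell in both adjustments (median 0.73, camera 0.00899, adjusted p = 0.506 with an estimated correlation), with Gli1 at 2.36, Gli2 at 1.60 and Gli3 at 1.26. Of 18 interferon-induced genes 2 fell and 0 rose in both adjustments (median -0.65, camera 0.00737, adjusted p = 0.609 with an estimated correlation), Ifit3 by 2.83 and Rsad2 by 2.16, and the list call was lost without Wnt7acre replicate 3 (0.317) or ePRBoe replicate 3 (0.0843). Luminal epithelium markers had 1 rise and 3 falls of 20, and 1 and 4 adjusted over the list alone (median -0.05, camera 0.0437, adjusted p = 0.506 with an estimated correlation), with Elf3 at 1.01, Spint1 at -1.22 and Klf5 at -0.75. In the tight junction list 1 of 22 fell (Cldn8, -1.03), and none passed adjusted over the list alone where 6 had an unadjusted p under 0.05 (median -0.12, camera 0.0242, adjusted p = 0.506 with an estimated correlation), while Cldn3 (0.25, adjusted p = 0.583) and Cldn7 (0.34, 0.516) did not pass. Fkbp5, Gli2, Gli3, Ifit3, Rsad2, Elf3, Spint1, Klf5 and Cldn8 lost the call without Wnt7acre replicate 3 (adjusted p = 0.0989 for Elf3 to 0.344 for Rsad2). The luminal list call was lost without Wnt7acre replicate 1 (0.0642) or 2 (0.0783), ePRAoe replicate 1 (0.0656), 2 (0.203) or 3 (0.0914) or ePRBoe replicate 2 (0.0686) or 3 (0.0538), and the tight junction call without Wnt7acre replicate 2 (0.0556), ePRAoe replicate 2 (0.0989) or ePRAoe replicate 3 (0.0650). Over genes with a mean of at least 5 FPKM camera did not call the lists of cell cycle (median 0.19, 0.190), hedgehog (0.31, 0.662), interferon-induced (-0.44, 0.147), luminal (-0.05, 0.155) or tight junction genes (-0.15, 0.147).

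In lists that camera did not call (its p in brackets), the counts were the same adjusted over the list alone unless given. Of the implantation genes 4 rose and 1 fell of 27 (0.619), with Hoxa11 at 2.48, Hand2, a stromal factor, at 2.21 (3.5 ± 1.36 to 16.1 ± 3.37 FPKM), Hoxa10 at 1.66 and Msx1 at 1.47. Hoxa11, Hand2 and Hoxa10 are stroma markers too, so their rises are also counted in that list. Estrogen-induced genes had 3 rises and 1 fall of 17, and 4 and 3 adjusted over the list alone (0.658), with Igf1 at 2.20, Padi2 at 2.83 and Wnt7b at -3.00. The Wnt pathway list had 3 rises and 1 fall of 22 (0.462), with Lef1 at 2.24, Wnt6 at 1.59 and Tcf7 at 1.35. Prostaglandin genes had 3 rises and 1 fall of 13 (0.131), with Pla2g10 at 2.78, Ptgds at 3.37, Hpgd at 1.36 and Ptger2 at -0.91. Steroid receptor genes had 3 rises of 14 (0.467), Pgr and Fkbp5 among them. Ion transport genes had 2 falls of 17 (0.467), Scnn1g (-2.44) and Slc12a2 (-1.27), and gland markers 1 fall of 8 (0.792), Gpx3. No EGF receptor gene or ligand passed in limma, 3 having an unadjusted p under 0.05 and 1 rise and 2 falls passing adjusted over the list alone (0.265): Areg stood at 2.96 (adjusted p = 0.0925) and Erbb2 at -0.25 (0.592). No immediate early or heat shock gene passed, 2 having an unadjusted p under 0.05 (0.467), with Hsp90aa1 at -0.02 and Hspb1 at -0.38. None of 20 cholesterol synthesis genes passed, 3 having an unadjusted p under 0.05 (0.710), with Pmvk at 1.24 (adjusted p = 0.336) and Dhcr7 at 0.32 (0.419). Hoxa10, Msx1, Wnt7b, Wnt6, Tcf7, Pla2g10, Ptgds, Hpgd, Ptger2, Slc12a2 and Gpx3 lost the call without Wnt7acre replicate 3 (adjusted p = 0.0531 for Hoxa10 to 0.341 for Gpx3), Igf1 without ePRAoe replicate 2 (0.0525), and Padi2 without ePRBoe replicate 1 (0.0571) or 3 (0.061).

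Of the 1098 calls 95.7% had no overlap of libraries, against 39.8% of all genes and 10% by chance, a share that the choice of calls favours. The count was 231 without Wnt7acre replicate 3, 365 without ePRAoe replicate 2, and 582, 395 and 477 without ePRBoe replicates 1, 2 and 3. All 3 ePRBoe libraries came from run 1, which held 1 Wnt7acre library, so the rest of this comparison rests on the run differences seen in Wnt7acre and ePRAoe. The surplus of rises changed with the scaling: 619 rose and 479 fell with median-of-ratios factors (56.4% rose), 568 and 451 with quantile normalization (55.7%), and 668 and 261 with TPM. The median log2 fold change of all genes was 0.10 as deposited and -0.03 with median-of-ratios factors. Of the 60 called genes named besides Pgr, 18 passed with any 1 library left out.

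**Figure D3:**
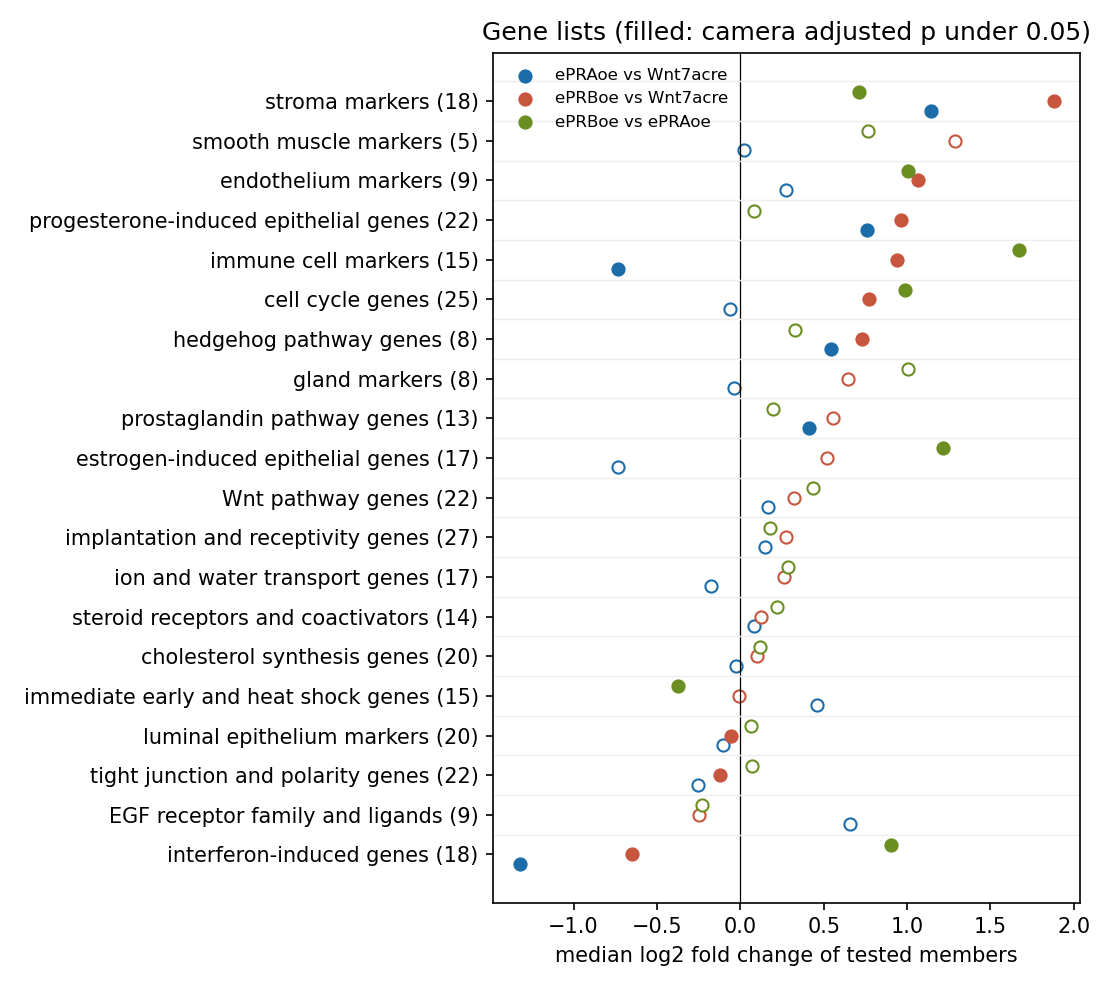
Median log2 fold change of the tested members of each gene list in the 3 comparisons, with filled symbols for lists that camera called at a preset correlation. Stroma markers had medians of 1.14, 1.88 and 0.71, and immune cell markers of -0.73, 0.94 and 1.67.

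The comparison of ePRBoe with ePRAoe asks where the isoforms differ. Of 15 immune cell markers 6 were higher in ePRBoe, among them Tyrobp, Nkg7 and Cd52 (camera called the list, adjusted p = 0.168 with an estimated correlation). Calca, Guca2b and Lcn2 were also higher. In total 39 genes rose and 1 fell (40), and 2310 had an unadjusted p under 0.05. Calca rose by 4.49 (0.201 ± 0.0872 to 30.8 ± 21.5 FPKM, SD, n = 3, adjusted p = 0.039). Guca2b, which signals through guanylate cyclase, rose by 3.08 (8.7 ± 8.71 to 35.9 ± 3.92 FPKM, adjusted p = 0.0224) and Lcn2, an iron-binding secreted protein, by 2.84 (25 ± 15.6 to 76.2 ± 29.2 FPKM). These folds are adjusted for the run, so they need not match the plain means. Over the settings run they ranged from 2.28 to 3.31 for Guca2b and from 1.74 to 3.21 for Lcn2. Tyrobp rose by 2.61 (23.2 ± 7.29 to 95 ± 10.4 FPKM, adjusted p = 0.0107), Nkg7 by 2.40 and Il2rb, the interleukin 2 receptor chain of natural killer cells, by 2.26. Lancl3 rose by 2.54, AW112010 by 2.33, Klra7 by 2.21 and Cd52 by 2.19. March6, a ubiquitin ligase, alone fell (-1.23, 59.6 ± 19.3 to 30.6 ± 1.32 FPKM, adjusted p = 0.0224). Below the threshold stood Styk1 (-1.24), Alpl (-2.74) and B3gnt5 (-1.49), each with adjusted p = 0.0706, Dhx33 (-0.84, 0.0794) and Enpp4 (-1.24, 0.0811).

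All 15 immune cell markers rose adjusted over the list alone, and 6 over all genes, Fcer1g by 1.73 and C1qc by 1.67 among them (median 1.67, camera 4.88e-15, adjusted p = 0.168 with an estimated correlation). In each of the next 5 lists no member passed over all genes in limma. Stroma markers had 5 rises adjusted over the list alone and 8 with an unadjusted p under 0.05 (median 0.71, camera 0.000116, adjusted p = 0.677 with an estimated correlation), with Vim at 0.80 (adjusted p = 0.195) and Sparc at 1.23 (0.238). Cell cycle genes had 12 and 14 (median 0.99, camera 0.000128, adjusted p = 0.677 with an estimated correlation), though Pcna (0.20, adjusted p = 0.472) and Top2a (0.12, 0.907) did not pass. Endothelium markers had 2 and 3 (median 1.00, camera 0.00969, adjusted p = 0.681 with an estimated correlation; Cdh5 1.39, adjusted p = 0.0885). Interferon-induced genes had 0 and 6 (median 0.90, camera 0.0327, adjusted p = 0.681 with an estimated correlation; Bst2 1.33, adjusted p = 0.126). Immediate early and heat shock genes were lower (median -0.37, camera 0.00227, adjusted p = 0.677 with an estimated correlation), with 4 falls at an unadjusted p under 0.05. Of 17 estrogen-induced genes Lcn2 rose, and 6 rose and 1 fell adjusted over the list alone (median 1.21, camera 0.0327, adjusted p = 0.677 with an estimated correlation; C3 2.27, adjusted p = 0.173). Progesterone-induced genes did not differ as a list (median 0.08, camera 0.868, 2 rises adjusted over the list alone), with Calca as the called member and Hdc (-0.40, adjusted p = 0.487) and Alox15 (-0.47, 0.582) not passing. The other 12 lists had no called member, at most 4 (Wnt pathway) that rose adjusted over the list alone and camera p from 0.138 to 0.949, with Des at 1.44 (adjusted p = 0.058), Areg at -0.23 (0.911) and Ihh at -0.22 (0.779).

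Each of the 40 calls had no overlap of libraries, against 22.6% of all genes and 10% by chance, which the choice of calls favours. The count depended on single libraries: it was 576 without Wnt7acre replicate 1, 540 without ePRAoe replicate 1, 22 without Wnt7acre replicate 2 or ePRAoe replicate 3, 9 without Wnt7acre replicate 3 and 24 without ePRBoe replicate 3. It was 0 in limma without ePRAoe replicate 2, ePRBoe replicate 1 or ePRBoe replicate 2, where 890, 1430 and 1624 genes had an unadjusted p under 0.05. Run 1 held all ePRBoe libraries and 1 ePRAoe library, and the count was 7 with no run term and 10 with the run as a random effect. Of the 13 called genes named here 3 passed with no run term and 0 in both fits with a replicate block. None of the 13 passed with every library left out in turn; without ePRAoe replicate 2 Tyrobp had the lowest adjusted p among them (0.189). The immune and cell cycle list calls held with any 1 library left out, but over genes with a mean of at least 5 FPKM the cell cycle list did not pass (median 0.20, camera 0.414). Without ePRAoe replicate 2 the stroma, estrogen, endothelium, interferon and immediate early lists did not pass (0.366, 0.976, 0.976, 0.976 and 0.986, the last with a median of 0.20); the estrogen, endothelium and interferon lists also failed without Wnt7acre replicate 1 (0.121, 0.10 and 0.226) or ePRAoe replicate 1 (0.123, 0.101 and 0.244), and the interferon list without ePRBoe replicate 1 (0.0947) or 2 (0.130). With median-of-ratios factors 20 genes rose and 2 fell, with quantile normalization 14 and 1, and with TPM 24 and 1. The median log2 fold change of all genes was 0.15 as deposited and -0.02 with median-of-ratios factors.

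**Figure D4:**
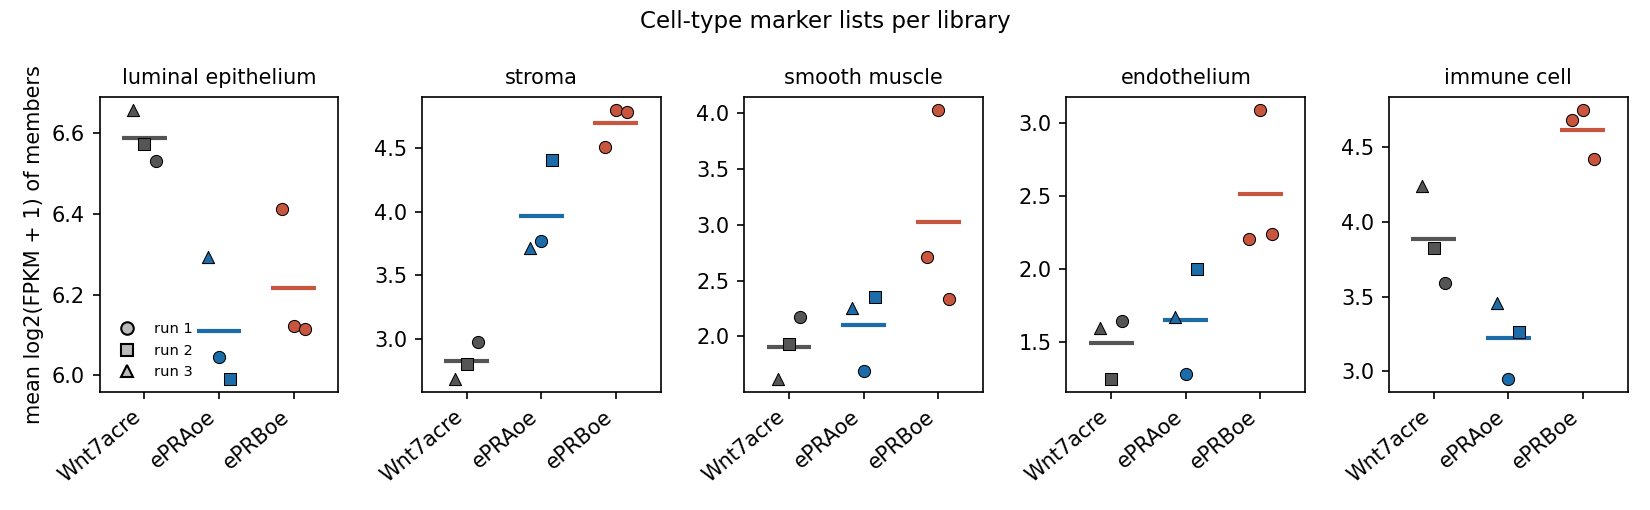
Mean log2(FPKM + 1) of the luminal epithelium, stroma, smooth muscle, endothelium and immune cell marker lists in each library. Stroma scores were 2.69 to 2.98 in Wnt7acre, 3.71 to 4.41 in ePRAoe and 4.51 to 4.80 in ePRBoe, and immune scores were 3.59 to 4.24, 2.95 to 3.46 and 4.42 to 4.75.

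The changes of both genotypes against Wnt7acre overlapped. Of the genes tested 376 rose and 280 fell in both comparisons (656), against 57.0 and 27.5 if the calls were independent, with Spink8, Drd4, Gata2 and Hsd11b2 up and Gabrp, Depp1, Wnt7b and Ifit3 down in both. In opposite directions went 8 genes, picked out after their values were seen: Tyrobp, Fcer1g, Gngt2, Selplg, AW112010, Rab34 and Galns fell in ePRAoe and rose in ePRBoe, and March6 did the reverse. Log2 fold changes correlated at 0.727 across genes, which are not independent replicates, and 70.3% had the same sign. Both comparisons use the same 3 Wnt7acre libraries, which alone gave a correlation of 0.408, the same sign in 63.4% of genes and 0.01 shared calls on average over 100 simulations without any effect. The covariance was 0.342 against 0.0283 in the simulations. With no library shared, the log2 fold changes of ePRAoe within runs 2 and 3 (2 libraries against 2) and of ePRBoe within run 1 (3 against 1) correlated at 0.707, with a covariance of 0.337 and the same sign in 68.9% of genes. Calls were not compared in this way, so part of their overlap can come from the shared controls. Stroma markers rose in both comparisons (11 and 14 of 18). More stromal RNA in both sets of captures could also give part of the overlap and of these correlations, and was not told apart from isoform effects. The count of shared calls was 349 without Wnt7acre replicate 2, 151 without Wnt7acre replicate 3, 246 without ePRAoe replicate 2, 375 without ePRAoe replicate 3, and 411, 266 and 308 without ePRBoe replicates 1, 2 and 3.

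The list calls rest on the preset correlation: with an estimated one camera called 0 lists in each comparison, with 0, 2 and 1 lists at an unadjusted p under 0.05, and fry called 6, 9 and 1. At the preset value the counts were 6 of 20 lists for ePRAoe against Wnt7acre (4 higher, 2 lower), 9 for ePRBoe against Wnt7acre (6 and 3) and 7 for ePRBoe against ePRAoe (6 and 1). The median, mean and camera direction of a list differed in sign in 11 cases, none of them called.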

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

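The stroma score as a covariate and the fit without run 3 were chosen only after the results had been seen. The edgeR test foreseen for whole read counts was not run, because the table holds FPKM. Leaving out a library of run 2 or run 3 leaves its partner alone in that run, where the run term takes it up. Without Wnt7acre replicate 3 or ePRAoe replicate 2, run 1 likewise drops out of ePRAoe against Wnt7acre. Pgr in that comparison was 2.20 with either of these left out, 1.97 for either library of run 2 and 2.96 for either of run 3. Losses listed for both libraries of a run are thus not separate there. Without Wnt7acre replicate 3, ePRBoe had no control in its run and was set against Wnt7acre through ePRAoe.

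Against Wnt7acre Pgr kept its direction under each setting that was run. It passed in ePRAoe under all of them but the stroma score (1.31, adjusted p = 0.840), with 1.97 to 2.96 when 1 library was left out. The ePRBoe call ended with the replicate block together with the run term (2.32, adjusted p = 0.0780), with the stroma score (0.50, 0.983), and without Wnt7acre replicate 3 (1.92), ePRAoe replicate 2 (2.45), ePRBoe replicate 2 (2.31) or ePRBoe replicate 3 (2.19), in a leave-one-out range of 1.92 to 2.56. The difference of ePRBoe from ePRAoe ranged from -0.39 to 0.25 when 1 library was left out.

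With 1 library left out, the genes changed ranged from 723 (without Wnt7acre replicate 3) to 2705 in ePRAoe against Wnt7acre, from 231 (without Wnt7acre replicate 3) to 1604 in ePRBoe against Wnt7acre and from 0 to 576 (without Wnt7acre replicate 1) in ePRBoe against ePRAoe, where limma gave 0 without ePRAoe replicate 2, ePRBoe replicate 1 or ePRBoe replicate 2 with 890, 1430 and 1624 at an unadjusted p under 0.05. The genes shared by both comparisons ranged from 151 to 954, and the lists called from 4 to 6, 6 to 11 and 2 to 8. Of the called genes named in the report besides Pgr, 43 of 76, 18 of 60 and 0 of 13 passed with any 1 library left out, and 72, 50 and 7 under each of the 3 scalings. With no run term 61, 50 and 3 of them passed, and 52, 31 and 0 in both fits with a replicate block. Of the called lists, 4 of 6, 5 of 9 and 2 of 7 passed with any 1 library left out. The list of immediate early and heat shock genes changed sign between ePRBoe and ePRAoe without ePRAoe replicate 2 (range -0.77 to 0.20).

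Other settings moved several counts. For ePRBoe against ePRAoe the 40 genes became 19 with no filter, 25 with TPM, 22 with median-of-ratios factors, 15 with quantile normalization, 7 with no run term, 10 with the run as a random effect, 491 in run 1 alone, 585 with only the 2 groups compared, 220 with array weights and 579 without run 3. For ePRBoe against Wnt7acre the 1098 genes became 653 at a mean of at least 5 FPKM, where fewer genes were tested, 1786 with no run term and 1728 with the run as a random effect. For ePRAoe against Wnt7acre the 1998 became 1041 in run 1 alone and 1116 with only the 2 groups compared. Run 1 alone holds 1 Wnt7acre and 1 ePRAoe library, so its counts assume that each varies like the 3 ePRBoe libraries. List counts became 3 of 9 for ePRBoe against Wnt7acre at a mean of at least 5 FPKM. Between ePRBoe and ePRAoe they became 4 (no run term) and 1 (fry) of 7. With an estimated correlation camera called 0 lists in each comparison, where 0, 2 and 1 had an unadjusted p under 0.05 and fry called 6, 9 and 1. Under fry the EGF receptor list passed as lower in ePRAoe against Wnt7acre (adjusted p = 0.0404), against the sign of its median (0.66) and the direction of camera, which had placed it above other genes without calling it (0.948). Among the lists called by camera, fry did not call hedgehog and interferon-induced genes in ePRAoe against Wnt7acre, luminal, endothelium, tight junction and interferon-induced genes in ePRBoe against Wnt7acre, or any list but the immune one between ePRBoe and ePRAoe (cell cycle 0.0850). With no run term the prostaglandin list in ePRAoe against Wnt7acre (0.0523) and the estrogen, interferon and immediate early lists between ePRBoe and ePRAoe (0.10, 0.284 and 0.0772) did not pass. Apart from the settings with fewer genes or samples, the cause was not tested.

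The replicate numbers of the labels did not pair the libraries: of 9 pairs with the same number 2 correlated above 0.1 once group means were removed (-0.230 to 0.171), and 1 of 9 libraries was closest to one with its own number. With a replicate block in place of the run term 1113 genes changed in ePRAoe against Wnt7acre and 4 in ePRBoe against ePRAoe, where 4 lists were called. With the replicate block together with the run term the counts were 917, 282 and 0 (limma, 1212 at an unadjusted p under 0.05), with 199 shared genes.

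The stroma score left little of the genotype to test, since group and run explained 96.0% of its variance. With it limma called 0 genes in each comparison (715, 647 and 1342 at an unadjusted p under 0.05) and 0 shared genes, and camera called 2 lists in each comparison with ePRBoe. The stroma list itself is set by its own score: 0.18 in ePRAoe and 0.12 in ePRBoe against Wnt7acre, and -0.0760 between ePRBoe and ePRAoe. In ePRAoe against Wnt7acre these medians or log2 fold changes changed sign or list direction: endothelium (-1.54), hedgehog (-0.00527), Wnt7a (0.0910), Lpar3 (-0.20), Calb1 (-0.74), Top2a (-0.19) and Pla2g10 (-0.0721). In ePRBoe against Wnt7acre they were progesterone-induced genes (-0.36), luminal epithelium (0.46), endothelium (-1.63), tight junction (0.43), hedgehog (-0.0162), Gpx3 (0.98), Zfp750 (0.16), Igf1 (-0.91), Hoxa10 (-0.91), Spint1 (0.30), Cdh5 (-0.33), Eng (-0.10), Mki67 (-0.30), Gli2 (-1.14), Pla2g10 (-1.18) and Hpgd (-0.32). Between ePRBoe and ePRAoe the endothelium list was at -0.0793. The low counts follow from the shared variance of score and genotype, and the cause of the sign changes was not tested.

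In simulated data with 200 genes changed, 3.08%, 0% and 0% of genes changed by 1.5-fold were recovered in the 3 comparisons. Most changes of that size would be missed in such data. The real comparisons gave 1998, 1098 and 40 calls, against 107, 77 and 72 in the simulations. The adjusted threshold depends on that number, so the recovered shares need not carry over. How much of the low recovery comes from depth, and how much from the number of libraries or the spread between them, was not tested.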

Other observations

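The gene families and the tests of the immune markers between runs, of immune against stroma markers in each comparison, of the Wnt7acre differences against the run and of the stroma markers between Wnt7acre libraries were chosen only after the results had been seen. The tests of the second stroma list and of the other splits had been set out beforehand.

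Among 8 gene families picked out for their values 2 are described here, with no list test, since they were chosen for what such a test would ask. Of 40 tested replication-dependent histone genes (Hist1h), which are transcribed in S phase, 18 rose and 0 fell in ePRBoe against Wnt7acre (median 1.08), while in ePRAoe none passed in limma, with 7 higher and 1 lower at an unadjusted p under 0.05 (median 0.23). Between ePRBoe and ePRAoe 6 rose (median 0.98), but 13 without Wnt7acre replicate 1 or ePRAoe replicate 1 and 1 without Wnt7acre replicate 3 or ePRBoe replicate 3. Without ePRAoe replicate 2, ePRBoe replicate 1 or ePRBoe replicate 2 it was 0 in limma, with 23, 17 and 25 higher at an unadjusted p under 0.05. Hist1h1b, a linker histone, rose by 2.37 in ePRBoe (5.46 ± 2.26 to 19.6 ± 1.77 FPKM, SD, n = 3) and Hist1h2bl by 2.15. The direction was the same under each of the 3 scalings (12 to 18 rose against Wnt7acre), and the count against Wnt7acre was 5 without Wnt7acre replicate 3, 12 without ePRAoe replicate 2, and 9, 11 and 9 without ePRBoe replicates 1, 2 and 3. Of 6 granzyme genes, the cytotoxic proteases of natural killer cells, 3 rose in ePRAoe (median 1.54) and 4 in ePRBoe (median 2.47), the latter 2 without Wnt7acre replicate 3. Gzmb rose by 1.77 and 2.43 and Gzmc by 1.84 and 3.26, in the same direction under each scaling. In ePRAoe these rose while Tyrobp and Fcer1g fell, and which cells carried them was not tested.

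Of 18 stroma markers 11 were higher in ePRAoe and 14 in ePRBoe than in Wnt7acre. Less epithelium in the captures would raise the markers of every other cell type. In ePRAoe the immune median fell (-0.73) while the stroma median rose (1.14). They lay apart by 1.88 (spread 0.640), which argues against less epithelium as the whole cause in ePRAoe. The spread here and below is the root of the summed squares of the SDs over the members of both lists. It measures genes and not libraries or mice. In ePRBoe the stroma, smooth muscle, endothelium and immune medians were all above 0 (1.88, 1.29, 1.07 and 0.94). Stroma and immune medians lay apart by 0.941 there (spread 0.797), which argues against an equal rise but leaves less epithelium open as a cause. A second stroma list of 24 genes, sharing none with the first, moved as stromal cells in the captures would have it: medians were 0.860 in ePRAoe (11 rose and 2 fell of 22 tested) and 1.70 in ePRBoe (14 rose, 0 fell), above the bounds of 0.597 and 1.29. Laser capture is the step meant to exclude such cells, yet 17 of the 18 markers already had a mean of at least 1 FPKM in Wnt7acre. Of the markers 4 (Hand2, Hoxa10, Hoxa11 and Nr2f2) stand in another list too. The most abundant in ePRBoe, Sparc, Vim and Col3a1, went from 19.3, 21 and 15.6 FPKM in Wnt7acre to 86.2, 70.8 and 66.7 in ePRBoe. More stromal RNA in the captures therefore stays a candidate explanation, and a change of these genes within the epithelium, which the genotypes could bring, was not tested.

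The 15 immune cell markers had a median difference of 1.38 between ePRBoe and ePRAoe without a run term, and all ePRBoe libraries came from run 1. The run 1 libraries of Wnt7acre and ePRAoe, 1 each, did not have higher markers than those of the other runs: the median differences were -0.296 and -0.471 in Wnt7acre and -0.297 and -0.633 in ePRAoe (SD over members 0.473 to 0.60), which argues against the sequencing run as the cause. Immune and stroma medians lay apart by 0.960 (spread 0.603), which argues against a lower share of epithelium that raises every other cell type alike. Stroma, smooth muscle and endothelium medians were higher too (0.71, 0.77 and 1.00), so a lower share may give part of the immune difference. More or other immune cells in the ePRBoe captures, fewer in the ePRAoe captures, and an effect of the isoforms on those cells may each give that difference and were not told apart.

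The Wnt7acre libraries spread along the axis that separates the genotypes. The difference of Wnt7acre replicate 1 from 2 correlated across genes at 0.201 with the difference of the ePRAoe libraries of the same runs. That was below its correlations with the genotype differences within run 1 (0.364 for ePRAoe, 0.310 for ePRBoe). The difference between ePRAoe libraries holds no genotype effect and may be mostly noise, which would lower its correlation. Each difference also rests on few libraries, so this does not decide whether the run was the cause. A test on genes weakly correlated with the stroma score decided nothing, since group and run explained 96.0% of that score. Over the 7079 genes with an absolute correlation of at most 0.5, the Wnt7acre difference correlated at 0.233 with the ePRAoe difference within run 1. At limits of 0.3, 0.2 and 0.1 it correlated at 0.140, 0.109 and 0.137. Replicate 1 lay nearer to the overexpressing libraries, yet its stroma markers stood at a median of -0.184 (SD 0.688, 6 of 18 above 0) relative to replicate 2, where that position on the first component would need 0.574, which argues against different shares of stroma as the whole cause. The hour of collection within day 4 and the response of each mouse to progesterone stay open and untested, and the run stays open too.

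With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1998 changed genes in ePRAoe against Wnt7acre with 1 at most in any other, 1098 in ePRBoe against Wnt7acre with 0 at most (limma), and 40 in ePRBoe against ePRAoe with 1 at most, so 1 of 10 splits, the real one, reached each count. The run term was kept, so some other splits set fewer libraries against each other within a run. A mixed split also puts the genotype difference into the residual spread. Both favour low gene counts in the other splits, so no conclusion is drawn from them. For the called lists, 6 in ePRAoe against Wnt7acre stood beside a highest of 7 in the other splits, and 4 of the 10 splits gave as many. In ePRBoe against Wnt7acre 9 stood beside 7, with 1 split as large, and in ePRBoe against ePRAoe 7 stood beside 8, with 5 splits as large.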
